A study of Mus musculus with 2 samples.

How the data were processed

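RNA of 2 cultures was measured on 1-colour (Cy3) mouse expression arrays, 1 array for the library labelled wild type and 1 for the library labelled Gfi1 knockout. Per the labels' protocols, 100 ng of total RNA was amplified and labelled for each array. Per the submitters' processing notes, the arrays were processed with Agilent Feature Extraction 11.5.1.1. Genotypes were taken from the samples' labels.

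The deposited files give the authors' intensity per spot under a column headed as raw, on a linear scale with up to 3 significant digits, together with the probe name and the feature number. What background correction these values carry is not given in the sources used here, and the files used hold no flags, background columns or control spots. A second deposited table by the authors gives an intensity per feature number. Its values are close to the per-array signals times a constant. The median ratio was 2.27 (range 2.26 to 2.28) for the library labelled wild type and 2.26 (2.24 to 2.27) for the other. The column medians of this table were 34.4 and 34.8. It is linear and not centred; how the constants were chosen stays unknown. The table was used as an alternative. Probe names matched between the per-array files for 100% of spots.

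Signals were put on the log2 scale and averaged over the spots of a probe, and each array's 75th percentile over probes was subtracted. A probe counted as detected on an array where its signal exceeded that array's median over probes (14.2 units for wild type, 14.6 for knockout by label). Without background flags this is a convention, and it calls 27838 and 27808 probes detected. Probes detected on neither array were left out, leaving 29363, of which 26283 were detected on both. An undetected side was set to the floor, and where all probes of a gene were undetected on a side its fold is given as a bound. A gene's value is the mean over its probes detected on at least 1 array. Signals quoted for genes are geometric means over those probes.

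Gene names came from the platform annotation, which lists 31465 spots with 1 symbol, 0 with several and 27840 without. Symbols were updated through unversioned accessions in a RefSeq gene table of assembly GRCm38.p6 for 29050 spots, through the symbol for 2061 and through a synonym for 349, and 5 kept the name in the annotation. This altered 3282 symbols. The files name no genome build, so no coordinates are given.

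With 1 array per genotype no test was possible and genes were counted by size, at a log2 difference of 1. The array count limits the precision. Spread within the arrays was measured over the spots of 399 probes printed on 10 spots and over different probes of a gene. For each of 32 gene lists fixed before the data were examined, the median difference of the detected members was placed among 10000 random lists of the same size matched in 10 classes of mean level. A list stands apart below percentile 2.5 or above percentile 97.5, and lists with under 5 detected members have values only. This describes these 2 libraries. Of 30 lists with a percentile 20 stood above, 3 below and 7 within. Lists share genes and are not independent.

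The genes that could be named were fixed by rule before the data were examined, and the text names a part of them. The rule takes every detected member past 2-fold of the T helper, GFI1 target, cytokine receptor and chemokine receptor lists; Gfi1, Tbx21, Ifng, Gata3, Foxp3 and Bcl6 whatever their value; the 15 largest differences each way; the 4 largest of each other list; and Actb, Gapdh, B2m and Hprt. An item of this rule is not reported here. Stat4, Ccl5, Cd8a, Cd8b1, Klrk1, Klrb1c, Ncr1, Zbtb16, Klra1, Fcer1g, Cd79a, Cd79b, Cr2, Cd22, Cd5, Cd3e, Cd4 (also a point of the signal plot), and the genes of the closing observations were chosen after their values were seen.

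Alternatives were scaling to the median, quantile normalization, cyclic loess (span 0.3), no scaling, the authors' table, other floors, probes detected on both arrays, the brightest probe or the median over probes, other fold thresholds and an offset of 16 units. Leaving out spots above feature number 50000 and leaving out sex-linked genes were added after the data were seen.

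The steps were tested on simulated data, in which 200 of 13184 genes of a comparison of 1 array against 1 were altered, with noise taken from the replicate spots. Of 50 genes altered 1.5-fold 0% were called at 2-fold, of 50 altered 3-fold 100%, of 50 altered 6-fold 98.0% and of 50 altered 12-fold 94.0%, and of 12984 unaltered genes 0.08%. Of 40 simulated lists of unaltered genes 2 stood apart. These lists were drawn at random from the genes that also form the reference lists, so the percentile limits set this share. It does not tell how often lists of genes that move together would stand apart. The noise of cultures and of late-numbered spots is not in this simulation. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.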

Results

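The series compared activated CD4 T helper cells labelled as wild type or as knockout for Gfi1, a zinc-finger repressor of transcription. According to the labels, naive CD4 T cells from C57BL/6 spleens were stimulated for 2 days with antibodies to the T cell receptor beta chain (3 µg/ml) and to CD28 (1 µg/ml). IL-2 (10 ng/ml) and antibodies that neutralise IL-4 (5 µg/ml), a T helper 2 cytokine, and IFN-γ (5 µg/ml), the T helper 1 cytokine, were present. How fully the antibodies blocked these cytokines was not measured. RNA of 1 culture labelled wild type and 1 labelled Gfi1 knockout was hybridised to 1-colour mouse expression arrays, 1 array each. The title of the series names the question, which is how Gfi1 bears on the T helper 1 programme. With 1 array per genotype no spread between animals or cultures can be had, and no p-value is given anywhere. Values are log2 differences, library labelled knockout minus library labelled wild type, after scaling. The SDs given are over different probes of a gene, and cover variation within the arrays alone.

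Each array gave 59305 spots of 55681 probes. The 75th percentile of the probe signals was 263 units in the library labelled wild type and 269 units in the library labelled knockout. Of 20738 genes with a named probe, 13411 were detected on at least 1 array. Among 399 probes printed on 10 spots, the median SD of the difference over spots was 0.35 at signals of 15 to 50 units, 0.11 at 50 to 500 and 0.05 at 500 to 5000. Over the 3655 genes with several detected probes, the median SD between probes was 0.10.

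The Gfi1 transcript itself was brighter in the library labelled knockout. Its single probe read 4260 units in the library labelled wild type and 18100 units in the library labelled knockout, a 4.15-fold difference (log2 2.05). A knockout removes or disrupts the gene, so this reading runs against the labels if the probe lies inside the deleted part. The place of the probe relative to the deletion is not given in the sources used here, and a probe outside it checks nothing. For this reason the libraries are named by their labels throughout, and every direction below rests on those labels.

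At least 2-fold differences covered 485 genes that were higher and 204 genes that were lower in the library labelled knockout, of 13411 detected. These are 3.62% and 1.52% of the genes. Of the higher genes 111 were detected only in the library labelled knockout, and of the lower genes 81 only in the library labelled wild type, so that their folds are lower bounds. Among the 6831 genes that reached 500 units on an array, 135 were higher and 16 were lower. Of the 109 genes with several detected probes and a mean past 2-fold, all 109 had these probes on the same side of 0, and 64 had every one past 2-fold. This agreement is partly built in. The genes were picked by the mean of the same probes, and probes detected on neither array had been left out. Dim spots with feature numbers above 50000 differed by 2-fold in 25.3% of cases, against 9.27% of equally dim spots with lower numbers. Without the spots above 50000, an alternative chosen after the data were seen, 351 genes were higher and 105 lower.

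**Figure D1:**
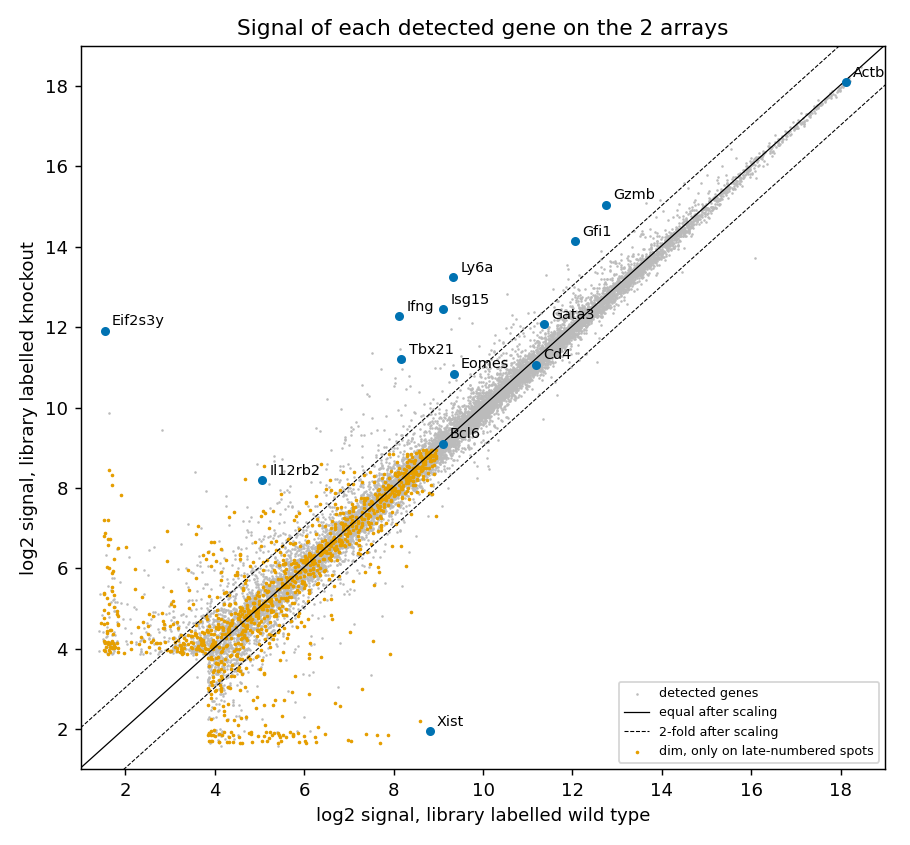
Log2 signal of each detected gene in the library labelled wild type (horizontal) and labelled knockout (vertical), 1 array each and before any floor, with lines for equality and for 2-fold after scaling; orange points are dim genes measured only on spots with feature numbers above 50000. Gfi1, Tbx21 and Ifng lie above the upper 2-fold line, at log2 differences of 2.05, 3.00 and 4.11, and Bcl6 lies at -0.02.

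Genes of the T helper 1 programme were higher together in the library labelled knockout. Ifng, the cytokine that defines these cells, read 279 units in the library labelled wild type and 4944 units in the other, a 17.3-fold difference, and its 2 spots gave differences with an SD of 0.01. Tbx21, which encodes the T helper 1 transcription factor T-bet, was 7.98-fold higher (289 against 2360 units, 1 probe). Il12rb2, a chain of the IL-12 receptor, was 8.53-fold higher (log2 3.09 ± 0.13, SD over 2 probes). The related T-box factor gene Eomes stood at 1.47 ± 0.08 (2 probes), the chemokine genes Ccl3 and Ccl4 at 2.67 and 2.31, and Il18r1 at 1.57 ± 0.17 (2 probes). Lta was 2.82-fold higher. Also past 2-fold were Il2 (2.14), Ly6c1 (2.90 ± 1.37, 2 probes), Nkg7 (1.07 ± 0.35, 2 probes) and Havcr2 (1.40), the last on a dim spot above feature number 50000. Tbx21, Ccl4, Il2 and Ly6c1, the last with 1 of its 2 spots dimmer than 500 units, were also read on spots above feature number 50000, where 2.45% of spots brighter than 500 units differed by 2-fold, against 1.92% at lower numbers. Of the 22 detected members of the list 12 were at least 2-fold higher and 0 at least 2-fold lower. Their median of 1.24 lay at percentile 100 of 10000 random lists matched on size and level. Stat4, the kinase-activated factor downstream of IL-12, differed by 0.10 and Ccl5 by 0.27. Markers of CD8 T and NK cells moved with this list, as given below.

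Other T helper lists were also higher, with smaller medians. The T helper 2 list had a median of 0.63 over 14 genes (percentile 100), with 4 genes at least 2-fold higher. These were Il13 (1.46), Il3 (2.20, on a dim spot above feature number 50000), Il9, which was at least 8.81-fold higher, and Gfi1 itself; without Gfi1 the median was 0.58 over 13 genes. Gata3, the factor of T helper 2 cells, stood at 0.68. The T helper 17 list had a median of 0.52 over 11 genes (percentile 99.97), and included Csf2 at 1.02. Il17a was at least 2.82-fold higher, from a signal below the floor in the library labelled wild type to 41.0 units. Tmem176a was at least 6.21-fold higher on a dim spot above feature number 50000. Tmem176b stood at 1.53 ± 0.94 (2 probes, 1 of them below the floor in the library labelled wild type). This list no longer stood apart with a floor at the 75th percentile of the probes, where its median was 0.03 (percentile 76.3). The regulatory T cell list had a median of 0.18 over 14 genes (percentile 99.8), with Foxp3 at 0.56, Lrrc32 at 1.02 and Nt5e at -1.19. The follicular helper list lay within the random lists, at -0.06 over 12 genes (percentile 47.6), with Bcl6 at -0.02, Cxcr5 at 1.13 and Ascl2 at -1.23. Both the list's median and Bcl6 passed 0 under other scalings of the arrays, as the median of all genes did (0.01 with cyclic loess), so the crossing does not set them apart from other genes.

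Transcription factors of T helper cells had a median of 0.57 over 32 genes (percentile 100), 0.56 over 31 without Gfi1. Beside Tbx21 and Eomes, those past 2-fold were Batf3 (1.78), Irf8 (1.24), Irf4 (1.04) and Gfi1. Genes reported elsewhere as targets of GFI1 had a median of 0.29 over 20 genes without Gfi1 (percentile 100), of which 16 were higher and 4 lower. Id1 (1.42), Il7r (1.40), Socs3 (1.35) and Irf8 were at least 2-fold higher. Hoxa9 stood at -0.78 ± 0.79, read by 2 dim probes, 1 of them below the floor in the library labelled knockout. Much of this list overlaps other lists, and the 7 detected members held by no other list had a median of 0.28 (percentile 98.1).

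Interferon-stimulated genes formed the list with the highest median among those given a percentile. Of 40 detected members 29 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.72 (percentile 100). Usp18, a protease that removes the ubiquitin-like protein ISG15, was 13.9-fold higher (184 against 2610 units). Isg15 stood at 3.30 ± 0.09 (2 probes), Oas1a at 3.20 ± 0.27 (2 probes) and Ly6a, which encodes Sca-1, at 3.89 (643 against 9730 units). B2m, the light chain of MHC class I and a member of the housekeeping list, stood at 0.64. Markers of CD8 T and NK cells and of B cells were higher in the same library, as given below.

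Genes of cytotoxic granules and of NK and CD8 T cells were higher as well. Gzmb, which encodes granzyme B, read 6900 and 34000 units, a 4.82-fold difference. Gzmc stood at 2.64 and Gzme at 3.30 ± 0.47 (2 probes). The cytotoxic list had a median of 0.83 over 20 genes (percentile 100), with 9 at least 2-fold higher. All 17 detected markers of CD8 T and NK cells were higher, 12 of them at least 2-fold, with a median of 1.46 (percentile 100). Of these, Klrk1, Klrb1c, Ncr1 and Cd8a lay below the floor in the library labelled wild type. Klra4, an NK receptor, stood at 2.13 and Klrc1 at 2.31 ± 0.56 (2 probes). In the library labelled wild type 1 of the 2 Klrc1 probes lay below the floor. Cd8a read 34.9 units in the library labelled knockout and lay below the floor in the other, and Cd8b1 read 244 and 127 units.

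**Figure D2:**
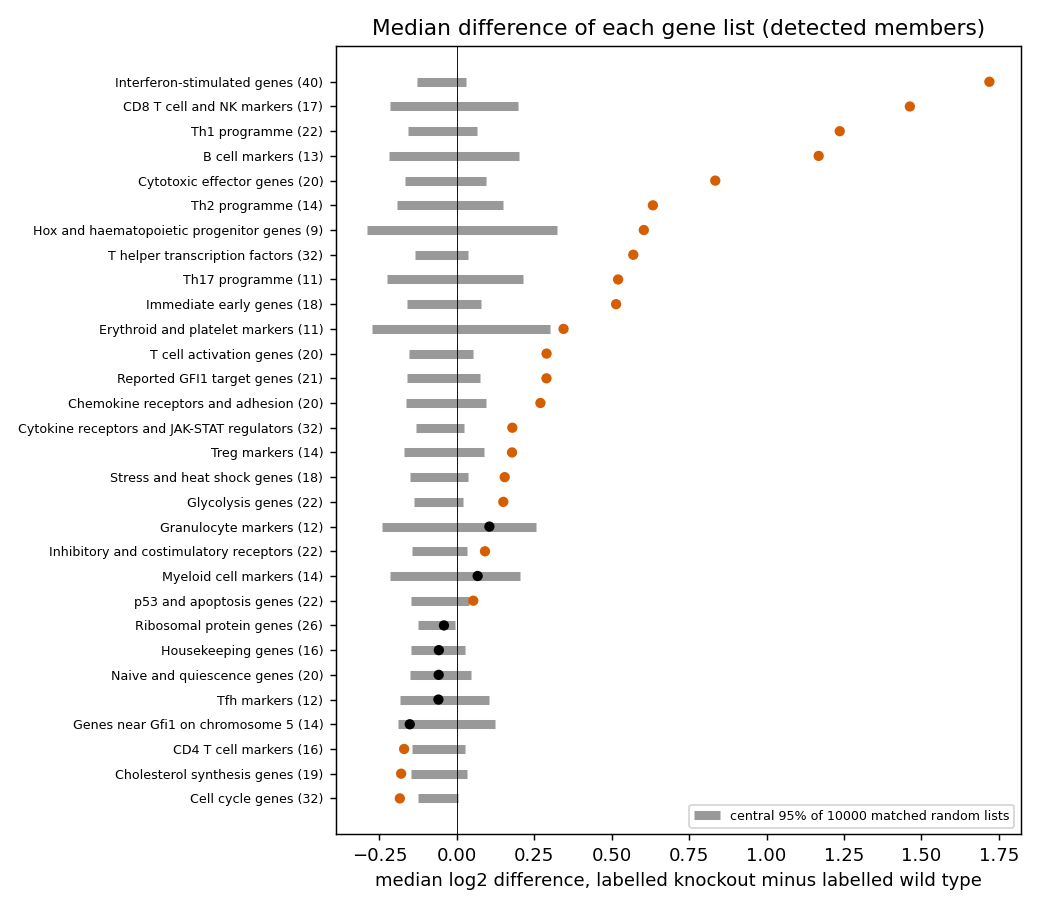
Median log2 difference of each gene list given a percentile (points; orange where the list stands apart from the random lists, black where it does not) with the central range of 10000 random lists matched on size and level (grey bars); the number of detected members follows each name. Among the 30 lists shown, which are those with a percentile, interferon-stimulated genes have the highest median, 1.72, and cell cycle genes the lowest, -0.18.

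Markers of other cell types differed too, although the labels describe isolated naive CD4 T cells. B cell markers had a median of 1.17 over 13 genes (percentile 100), and the 9 outside the T helper 1, interferon, cytotoxic and antigen presentation lists a median of 0.41 (percentile 99.1). Ms4a1 and Blnk stood at 3.52 and 3.62, at 221 and 386 units in the library labelled knockout, while Cd79b, a chain of the B cell receptor complex, stood at -0.17 (281 against 256 units). CD4 T cell markers had a median of -0.17 over 16 genes (percentile 0.73), of which 10 were lower and 6 higher. Cd5 and Cd3e, the lowest of these markers, both stood at -0.43, and Cd4 itself stood at -0.14 ± 0.03 (2 probes). Cd2 stood at 0.51 ± 0.08 and Cd247 at 1.85 ± 1.99. The 2 probes of Cd247 gave 0.45 and, on a dim spot above feature number 50000, 3.25. This list lay within the random lists without spots above feature number 50000, at -0.13 (percentile 7.14). Myeloid markers lay at 0.07 over 14 genes (percentile 82.0) but stood apart with a floor at the 25th percentile of the probes (0.41, percentile 99.9), with a floor at the 75th (0.25, percentile 99.6) and with the brightest probe per gene (0.19, percentile 98.7). Mpeg1 was at least 23.1-fold higher on its single detected probe. Granulocyte markers lay at 0.11 over 12 genes (percentile 83.6), with Mmp8 at least 7.30-fold higher on a spot above feature number 50000 and Chil3 at -1.57. Erythroid and platelet markers stood at 0.34 over 11 genes (percentile 98.5), which lay within the random lists without spots above 50000 (percentile 95.6), and haematopoietic progenitor genes at 0.60 over 9 (percentile 99.8). The members of these last 2 lists were mostly dim.

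Receptors and signalling genes showed moderate differences. Cytokine receptors and JAK-STAT regulators had a median of 0.18 over 32 genes (percentile 100), with Il10ra at 1.77, Socs1 at 1.11 and Socs3 at 1.35. Chemokine receptors and adhesion genes had a median of 0.27 over 20 genes (percentile 99.99). Ccr10 was at least 5.52-fold higher and Itgav stood at 1.15 ± 0.24 (2 probes). T cell activation genes had a median of 0.29 over 20 genes (percentile 100), with Il2 at 2.14, Nr4a3 at 1.46 and Cd40lg at 1.14. Egr3 was at least 11.1-fold lower, on a spot with feature number 62948. Immediate early genes stood at 0.51 over 18 genes (percentile 100), with Atf3 at 3.20, Fos at 1.86 and Jun at 1.05. Inhibitory and costimulatory receptors lay at 0.09 over 22 genes (percentile 99.8), with Cd274, which encodes PD-L1, at 1.39, Pdcd1 at -0.80 and Cd160 at -1.31. Naive and quiescence genes lay within the random lists at -0.06 over 20 genes (percentile 48.4), a median that crossed 0 under other scalings as that of all genes did, with Klf2 at -0.87 and Il7r at 1.40.

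Growth and metabolism lists differed little in size. Of 32 cell cycle genes 28 were lower and 4 higher, with a median of -0.18 (percentile 0.01) and 0 genes past 2-fold. Tyms stood at -0.59 and Cdc6 at -0.42 ± 0.13 (2 probes), whereas the cyclin genes Ccnd2 and Ccnd3 stood at 0.34 and 0.35. Cholesterol synthesis genes had a median of -0.18 over 19 genes (percentile 0.45), with Cyp51 at -0.34; without spots above feature number 50000 the list lay within the random lists, at -0.16 (percentile 3.30). Glycolysis genes had a median of 0.15 over 22 genes (percentile 100), with Egln3 at 2.40 ± 0.01 (2 probes), Aldoc at 1.25 and Hif1a at 1.12 ± 0.11 (2 probes). Of these, Egln3 and Hif1a encode regulators and not enzymes of glycolysis. Gapdh, an enzyme gene also in this list, stood at 0.04. Stress genes lay at 0.15 over 18 genes (percentile 99.98). Apoptosis and p53 genes had a median of 0.05 over 22 genes (percentile 98.6), a call that ended with the brightest probe per gene (percentile 96.1) and with a floor at the 25th percentile (percentile 97.0), and both members past 2-fold were lower, the pro-apoptotic Bmf (-1.45) and Bcl2l11 (-1.25). Ribosomal protein genes lay at -0.04 over 26 genes (percentile 78.0) and housekeeping genes at -0.06 over 16 (percentile 53.7). Gapdh stood at 0.04 ± 0.07 (8 probes), Actb at -0.05 and Hprt at -0.01. The ribosomal median, Actb and Hprt crossed 0 under other scalings, as the median of all genes did.

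Sex-linked transcripts separated the arrays. Xist, the RNA that coats the inactive X chromosome of females, read 447 units in the library labelled wild type and 3.86 units, below the floor, in the library labelled knockout. The Y-linked Eif2s3y was at least 266-fold higher in the library labelled knockout (2.91 against 3870 units), and Uty at least 2.09-fold higher. Genotype and these sex-linked readings therefore differ together in every comparison above. Leaving out X-linked and Y-linked genes, as an alternative chosen after the data were seen, left 463 higher and 193 lower genes. These counts cannot show whether sex bears on the autosomal differences. Genes near Gfi1 on its chromosome, in the order of assembly GRCm38.p6, had a median of -0.15 over 14 genes (percentile 7.14), with Ephx4 at -1.69 and Btbd8 at -1.11, each read by a single dim probe with a feature number above 50000. With only probes detected on both arrays this list stood apart, at -0.24 (percentile 0.26).

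Among the 15 genes with the largest positive differences, 8 were read only on spots with feature numbers above 50000, 5 of them dimmer than 500 units. Of the 15 largest negative differences 12 were read only on such spots, all 12 dimmer than 500 units. Tas2r115 and Drc3, at least 64.0-fold and 47.6-fold higher, lay at feature numbers 62194 and 62532, and a different Drc3 probe read 3.46 and 3.83 units. Slc8a1 was at least 27.2-fold lower on such a spot. Outside that range the largest positive differences were those of Eif2s3y, Mpeg1 and Ifng, and the largest negative ones those of Xist and Cd5l.

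**Figure D3:**
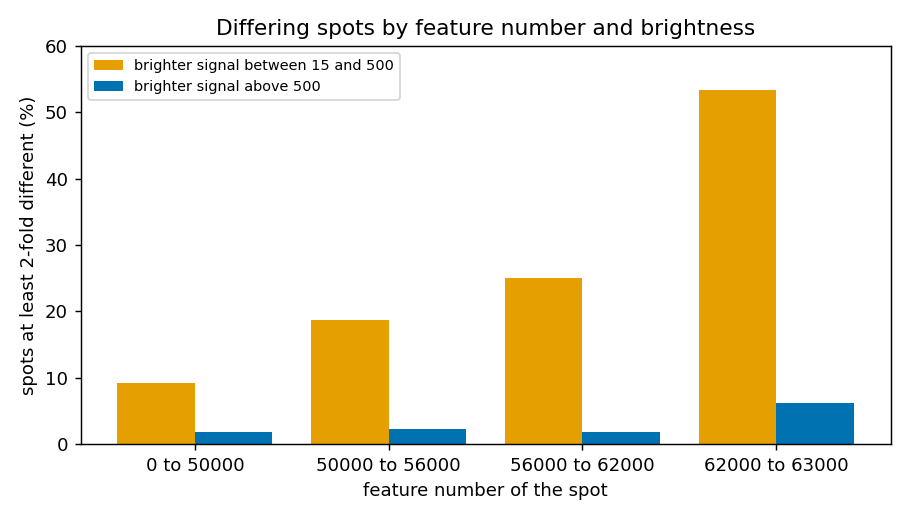
Percentage of spots at least 2-fold different between the arrays (vertical, bars from 0) by range of feature number (horizontal), for spots whose brighter signal lay between 15 and 500 units (orange) or above 500 units (blue). Among the dimmer spots the percentage goes from 9.27% up to number 50000 to 53.3% above 62000, against 1.92% and 6.22% among the brighter spots.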

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

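The tests in this part were chosen after the results they bear on had been seen, and the target, CD8 T and NK, and B cell lists were narrowed after their whole lists had been seen, the target list to members no other list holds and the others to members outside the lists of the pattern and of antigen presentation. Asking for every setting in the test of exchanged labels, and for detection under the wild-type label in the tests of other cells, was decided last, after earlier forms of these tests had been seen.

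Probes without a gene name entered none of the comparisons. Of 11485 such probes detected, 349 were at least 2-fold higher and 267 at least 2-fold lower in the library labelled knockout. They are given because these probes lie outside the main measurement. Without probes read only on spots above feature number 50000, 176 of 8767 were higher and 75 lower.

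Large differences gathered at dim spots with high feature numbers. Among probes printed on 10 spots, 35 of 1626 spot readings above feature number 50000 lay over 2 log2 units above their own probe's median, against 9 of 6354 below it, a ratio of shares of 15.2. The array with fewer such spots above 50000 still had 15. Spots of the same probe should read alike if expression differed between the genotypes, so these values argue against expression as the source of the pattern. A local excess of signal on single spots may be the source, and its physical origin stays open.

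The Gfi1 probe was brighter under the knockout label, at a feature number of 55280. The largest excess among outlying replicate spots was 187 units, far below the Gfi1 difference of 13840 units. This does not bound a local excess. Spots counted as outlying only over 2 log2 units above their own probe's median, so smaller excesses on bright probes went uncounted. Outside these probes, the late Drc3 spot read 7.01 units under the wild-type label and 691 under the knockout label. A different Drc3 probe read 3.46 and 3.83 units. A local excess on the Gfi1 spot therefore stays open. Exchanged labels could also give the higher Gfi1 reading, and would place genes repressed by GFI1 lower in the library labelled knockout. The 7 detected reported targets held by no other list had a median of 0.28 instead, above the central range of the random lists in 12 of 14 settings and at percentiles between 96.3 and 99.8 over all 14. Of these, Gfi1b lay below the floor under the wild-type label and could only come out higher, and Csf1 stood at 0.08 ± 1.05 over 3 dim probes. With only probes detected on both arrays 6 members were left, at 0.39 (percentile 99.5). With so few genes, reported as targets in other cells and not above that range in every setting, exchanged labels stay open; by the main setting alone (percentile 98.1) the test would have argued against them. A transcript of the altered allele that the probe still detects was not tested. Gfi1 is itself in the list of reported GFI1 targets, so the level of such a transcript could depend on GFI1, which was not tested either.

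T helper 1, interferon and cytotoxic genes were higher together. Outside the lists of this pattern and of antigen presentation, 12 CD8 T and NK markers were detected, of which 3 lay below the floor under the wild-type label and could only come out higher. All 9 others were higher too, but not all securely. Zbtb16 stood at only 0.11, against an SD of 0.35 over replicate spots of that level, Klra1 at 1.01 ± 0.98 over 2 probes, Klra7 had 1 of 2 probes below the floor under the wild-type label, and Fcer1g lay on a dim spot above feature number 50000. With these limits the count is consistent with some such cells in the culture labelled knockout, although the isolation of naive CD4 T cells should remove them and activated CD4 T cells can express several of these genes. These 12 markers read 17.5 to 252 units in the library labelled knockout, where Ifng read 4944 and Gzmb 34000 units. Whether CD8 T or NK cells could supply the T helper 1, interferon-stimulated or cytotoxic genes was not tested. Of the 20 detected cytotoxic genes 18 were higher and 2 lower. Cd160, a receptor gene of such cells outside the marker list, stood at -1.31. Of 8 B cell markers outside those lists that were detected under the wild-type label 7 were higher, of which Cr2 and Cd22 lay on dim spots above feature number 50000 and the 2 Cd79a probes gave 0.92 and -0.10. Cd79b stood at -0.17. Fcrl1, a B cell gene outside the list, stood at -2.97 (215 against 28.0 units, 1 probe). These markers go both ways, so that B cells stay open. The sex of the animals cannot be told apart from genotype, because each genotype has 1 array; X-linked genes as a whole had a median of -0.064. An effect of Gfi1 loss within CD4 T cells stays open beside these.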

How the results depend on the processing

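Leaving out spots above feature number 50000 and leaving out sex-linked genes were chosen after the data were seen. The log2 differences of the genes named by rule kept their sign under every alternative run for those past 2-fold. This is a weak check, because other scalings moved these differences by little and a higher floor or an offset mainly shrinks them. The count of lists standing apart stayed within 1.5 times the main 23. Counts depended on the threshold and on the treatment of dim probes; the cause was otherwise not tested. At 1.5-fold 1029 genes were higher and 570 lower, and at 4-fold 137 and 46, as a wider or narrower limit gives. Without a filter or floor the counts were 1004 and 638, with a floor at the 25th percentile 980 and 634, and with a floor at the 75th percentile 136 and 20. The lower genes numbered 125 with probes detected on both arrays, 117 with an offset of 16 units and 105 without spots above 50000. The median SD between probes was 0.15 without a filter and 0.053 with the floor at the 75th percentile. Erythroid and platelet markers went to -0.50 with that floor, where under 5 members were left. Myeloid markers stood apart with floors at the 25th (0.41) and 75th percentile (0.25) and with the brightest probe (0.19), and genes near Gfi1 with probes detected on both arrays (-0.24). Gfi1 and Tbx21 have no value without spots above 50000, since their probes lie there. Ccl4, Il2, Ly6c1 and Havcr2 of the T helper 1 list were also read only on such spots. So were 8 of the 15 largest positive differences and 12 of the 15 largest negative ones. Leaving these spots out could not check those readings. Background correction by normexp was not run, because the files used hold no background columns. No paired analysis was possible because each genotype had 1 library. Dim signals limit what can be read: the SD over replicate spots was 0.54 below 15 units and 0.04 above 5000.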

Other observations

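The genes grouped here were chosen after their values were seen, so only values are given and no test is made of the grouping. Genes of antigen presentation were higher in the library labelled knockout. All 8 detected genes of MHC class II presentation were higher, 7 of them at least 2-fold, with H2-Ab1 at 1.44, H2-Eb1 at 1.29 and Cd74 at 1.17. Of 17 genes of MHC class I presentation 16 were higher and 5 at least 2-fold, with H2-K1 at 0.46, Tap1 at 1.16 and the class I regulator Nlrc5 at 1.01. H2-Ab1, H2-Eb1 and Cd74 are also in the B cell list.

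Interferon-stimulated genes differed in size among themselves. The antiviral genes Mx1, Oas3, Irf7 and Rtp4 stood at 2.26, 2.45, 2.83 and 2.82, whereas the guanylate-binding protein genes Gbp2, Gbp3, Gbp4 and Gbp5 stood at 0.59, 0.38, 0.36 and 0.58. The family was not uniform, since Gbp6 stood at 1.93, Iigp1 at 2.49, Ifit2 at 0.20 and Ifih1 at -0.15. Antibody to IFN-γ was in the medium of both cultures.

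Transcripts known to escape X inactivation were lower in the library labelled knockout, which lacked Xist signal above the floor. The values of all 6 detected ones were below 0, with Kdm6a at -0.89 (1 probe) and Kdm5c at -0.59 ± 0.05 (2 probes). Ftx stood at -0.67 ± 0.50 and Eif2s3x at -0.08 ± 0.87 (2 probes each). Eif2s3x has no clear direction, since its spread between probes exceeds its difference. Erdr1, which is not among these 6 transcripts, read 69600 units in the library labelled wild type and 13600 units in the other (log2 -2.39, 1 probe). What lowers it was not tested. The 465 detected X-linked genes had a median of -0.06 and the 12925 autosomal genes a median of -0.05.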
